A study of Pinus pinaster with 24 samples.

How the data were processed

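RNA was measured in root tips of maritime pine (Pinus pinaster) seedlings that had received water or 3 mM ammonium chloride 24 h earlier. Per the labels' protocols, frozen root tips were cut into 30 µm sections, and 4 regions were collected by laser microdissection: root cap, meristem, developing vessels and developing cortex. cDNA was made and amplified with a SMART-Seq low-input kit and sequenced as paired reads of 150 bp. The 24 libraries are 4 tissues under 2 treatments in 3 experiments. The titles number the experiments 1, 3 and 4, and these numbers are used here. Libraries of the 4 tissues that share a treatment and an experiment number are called a set, which gives 6 sets. The labels do not say how many seedlings entered a library or whether the experiments used separate batches of plants, so p-values measure the spread between these libraries, which may be technical in part.

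The deposited values are a signal per transcript and library, reads divided by a scaled library size, as judged from the values. The columns sum to between about 793680 and 1210400 and differ between libraries, so the values are not plain CPM. In each library 100% of the values were whole multiples of the value of 1 read within a tolerance of 0.01 reads, and reads could be recovered. The divisor of each library matched an effective library size with edgeR's TMM factors up to a common factor, within 0.00311%. Per the submitters' processing notes, bcl2fastq and BWA were used, without versions. The counting program, the reference transcripts, the scaling and the filter are not given in the sources used here. The second-highest value of a transcript was at least 1.65 in the deposited values, so transcripts low in nearly all libraries had been removed. The table lists 47118 transcript identifiers and pairs 0 of them with a gene name. Gene lists fixed beforehand could therefore not be used, and transcripts appear under their identifiers.

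The recovered depth was about 67135000 to 88269000 reads per library. A floor of 3 reads corresponded to a deposited value of 0.0309 to 0.0493. Amplified reads without molecular identifiers are not independent molecules, and such floors cover counting error only. Transcripts with consecutive identifier numbers had a median correlation of 0.888 over the 24 libraries (31815 pairs), against -0.00696 for pairs far apart in identifier order. Counts of transcripts are therefore not counts of independent genes.

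Calculations used R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and plots used matplotlib 3.10.9. Values were analysed as log2(value + 1), so fold changes understate the change of low transcripts. Transcripts with a value of at least 1 in at least 3 libraries were kept, which left 46960 and removed 158. The planned design assumed CPM. As the values proved to be a scaled signal, the same log-scale test was used. The threshold was a Benjamini-Hochberg adjusted p under 0.05. The ammonium effect in each tissue was a limma contrast (empirical Bayes with trend) in a model of 8 groups over all 24 libraries, so that the groups shared an estimate of the spread. The effect averaged over tissues was tested on the 6 set means. The difference of the effect between tissues was a limma F test with the set as a block. A transcript was called enriched in a tissue when it passed the threshold with a log2 difference of at least 1 against each of the other 3 tissues, with the set as a block.

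For each tissue, up to 200 enriched transcripts with the greatest smallest difference to another tissue formed a list. The 4 lists were tested in the 4 ammonium contrasts (16 tests, adjusted together) with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. These lists were made from the same libraries. A list score per library was the mean of log2(value + 1) over a list made without that experiment, relative to the controls of the list's tissue in the other experiments. Scores of 3 ammonium and 3 control libraries were compared with 2-sided exact permutation tests, whose smallest possible p is 0.1. The rule for named transcripts was fixed before the data were examined: per ammonium contrast, the 2 greatest rises and the 2 greatest falls among called transcripts whose 3 ammonium libraries lay apart from the 3 controls, and per tissue the 2 with the greatest smallest difference.

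The procedures were tested on simulated reads with known answers. These reads were drawn independently per transcript, with the same dispersion in all groups and no shared deviation of a set. The real libraries had groups of unequal spread, correlated neighbouring transcripts and sets that deviated together, so false calls in them may be more numerous. With 50 transcripts changed at each fold size in the cortex among 46677 tested, the shared-spread fit recovered 8% at 2-fold, 62% at 4-fold, 74% at 8-fold and 88% at 16-fold, with 72 false calls. A fit of the 6 libraries of the tissue recovered 0%, 2%, 42% and 72%, with 6 false calls. Among 47118 transcripts, edgeR's quasi-likelihood test recovered 4%, 50%, 64% and 84% with 3 false calls, and DESeq2 20%, 70%, 82% and 98% with 132. With no ammonium effect simulated among 46714 transcripts, the shared-spread fit made 16 false calls in the root cap, 0 in the meristem, 93 in the vessels and 16 in the cortex, and the fit of 6 libraries made 0 in each. Most of these false calls, 15 in the root cap (93.8%), 91 in the vessels (97.8%) and 11 in the cortex (68.8%), were transcripts whose highest mean lay in the tested tissue. The averaged effect (46683 transcripts) was recovered at 26%, 80%, 88% and 98% with 8 false calls, and the difference between tissues (46677) at 0%, 14%, 40% and 74% with 28. Enrichment in the vessels (46622) was recovered at 4%, 76%, 86% and 94% with 0 false calls. That simulation gave each unchanged transcript the same mean in all tissues. Its 0 therefore does not cover transcripts that differ between some of the tissues. In all these simulations the changed transcripts were drawn only from those with a high mean value over the libraries. The recovery rates therefore do not cover low transcripts. The shared-spread fit had been fixed beforehand and was kept, and its false-call counts stand beside its calls.

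Alternatives were other pseudocounts, filters, scalings and thresholds, library weights, the experiment number as a block, the fit of 6 libraries, count tests on recovered reads, other list sizes, and leaving out each library, experiment or set. Leaving out 2 meristem ammonium libraries together, and leaving out each library in turn from the tissue comparison, were added after the data had been seen. No 2 libraries of a group held the same values (highest r 0.963), and each counted as 1 replicate, as labelled. Counting noise was not used to tell technical repeats apart, because repeats of amplified libraries at this depth would exceed it as well.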

Results

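Transcript levels were measured in 24 microdissected libraries from maritime pine root tips, with 3 libraries for each of 4 tissues in seedlings given water or 3 mM ammonium. The series asks how the tissues of the root tip differ and how each responds to ammonium after 24 h. Depth ran from about 67135000 recovered reads in the meristem control of experiment 1 to about 88269000 in the root cap control of experiment 4. Libraries of a group correlated with a median r of 0.935 across transcripts (range 0.824 to 0.963).

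Tissue accounted for most of the variation in transcript levels. It took 60.3% of the variance on the log2 scale (3 degrees of freedom), against 4.40% for ammonium (1 degree of freedom). The tissue by ammonium term took 4.11% (3 degrees of freedom) and the spread between libraries of a group 31.2% (16 degrees of freedom). Per degree of freedom, the tissue by ammonium term lay below the spread between libraries. The first component carried 44.3% of the variance, the second 21.6% and the third 9.30%. Spread between libraries was widest in the meristem ammonium group (root mean square SD 0.77 on the log2 scale) and the cortex ammonium group (0.67), and lay between 0.38 and 0.51 in the other groups.

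**Figure D1:**
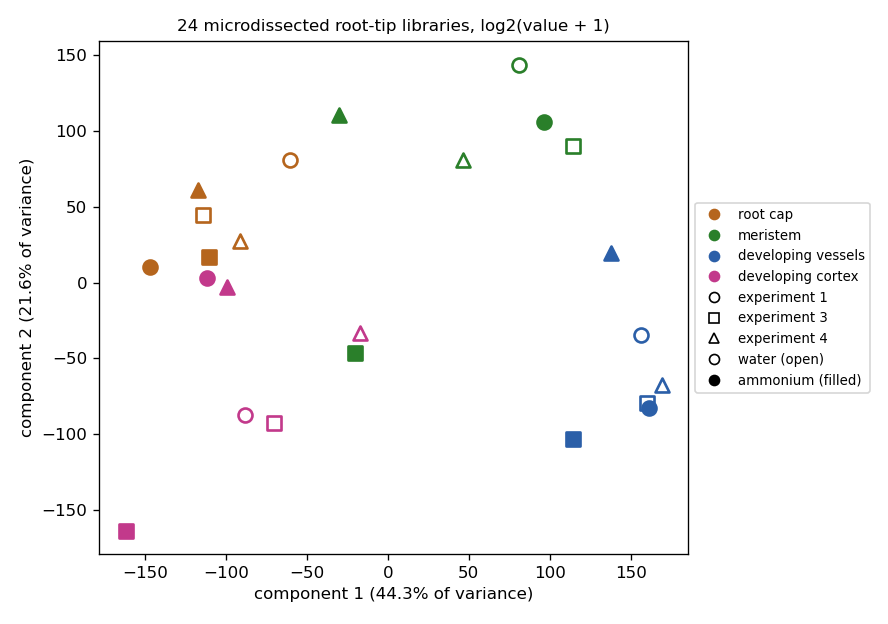
Scores of the 24 libraries on the first component (x axis, 44.3% of variance) and the second (y axis, 21.6%), without units, from log2(value + 1); each point is a library, colour gives the tissue, shape the experiment, and filled points received ammonium. The 6 vessel libraries lie at the right, and the meristem ammonium library of experiment 3 lies among the cortex libraries.

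Developing vessels had the most distinct transcript set. In them 3090 transcripts were enriched over each other tissue, 1158 of these by at least 2 on the log2 scale. The 2 leading vessel transcripts were nearly absent elsewhere: pp_155609 averaged 164 ± 70.3 (SD, n = 6) in vessels and 0.906 ± 1.39 in cortex, the closest tissue, and pp_203568 averaged 230.16 ± 155 and 1.62 ± 1.68. Their smallest log2 differences were 6.56 and 6.50 (limma adjusted p = 1.504e-10 and 1.9098e-10). The 3090 transcripts fell into 1576 runs of consecutive identifiers.

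The root cap had 916 enriched transcripts, 237 of them by at least 2 on the log2 scale. Transcript pp_114011 averaged 547 ± 480 (SD, n = 6) in root cap, 14.6 ± 35.1 in developing cortex and 4.34 ± 10.6 in meristem. Transcript pp_235229 averaged 401 ± 337 in root cap and 9.84 ± 23.2 in cortex, and was listed at 0 in all 6 vessel libraries. The smallest log2 differences were 6.96 and 6.63 (limma adjusted p = 0.000129 and 0.000111). Leaving out experiment 1 lowered the root cap count to 456, and leaving out experiment 3 lowered it to 571.

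Developing cortex had 862 enriched transcripts, 267 of them by at least 2 on the log2 scale. The leading transcripts pp_245636 and pp_245632 averaged 803 ± 927 and 634 ± 708 in cortex (SD, n = 6), with SDs above their means, against 32.9 ± 56.2 and 26.6 ± 45.8 in meristem. Their smallest log2 differences, against vessels, were 5.67 and 5.58 (limma adjusted p = 8.6516e-05 and 7.4904e-05). The cortex count fell to 484 without experiment 1 and to 361 without experiment 3.

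The meristem had the fewest enriched transcripts, 125, with 7 by at least 2 on the log2 scale. Transcript pp_177803 averaged 26.1 ± 19.9 (SD, n = 6) in meristem and 4.46 ± 3.47 in root cap, and pp_206002 averaged 20.3 ± 10.2 and 3.41 ± 1.76. The smallest log2 differences were 2.19 and 2.17 (limma adjusted p = 0.0155 and 5.0999e-05). The count rested on few libraries: it was 264 without the meristem ammonium library of experiment 3, 337 without that of experiment 4 and 895 without both, and 473 in control libraries alone. It was 64 without the meristem ammonium library of experiment 1, 58 and 56 without the meristem controls of experiments 1 and 3, 68 and 197 without the root cap ammonium libraries of experiments 1 and 3, and 23 and 194 without experiments 1 and 4. The call of pp_177803 ended without experiment 1 (adjusted p = 0.215), without experiment 3 (0.0577), and without the ammonium library of experiment 1 of root cap (0.0559) or meristem (0.0551), within a range of 0.00043 to 0.215 over its alternatives.

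Pairs of tissues differed to unequal degrees. Root cap and developing cortex were the closest pair by this count, with 3208 transcripts past the threshold (1429 higher in root cap and 1779 higher in cortex). Root cap and meristem differed in 5231 transcripts, of which 4456 were higher in root cap. Vessels differed from root cap in 10284 transcripts, from cortex in 10002 and from meristem in 6856. Meristem and cortex differed in 9480, with 6168 higher in cortex.

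In the root cap, 3 transcripts were higher after ammonium and 0 lower. Transcript pp_58601 averaged 4.76 ± 2.31 (SD, n = 3) with ammonium and 0.0661 ± 0.0726 with water, a log2 difference of 2.34 (SE 0.29, limma adjusted p = 0.0086). Its ammonium means were also above its control means in meristem (3.00 ± 1.42 against 0.00765 ± 0.0132), vessels (1.69 ± 0.389 against 0.045 ± 0.0395) and cortex (1.65 ± 0.882 against 0.164 ± 0.0441), where it did not pass the threshold. The second call, pp_119401, averaged 3.28 ± 2.02 with ammonium and 0.233 ± 0.0647 with water, a log2 difference of 1.70 (SE 0.25, limma adjusted p = 0.0341). Its call ended with pseudocount 0.1 (adjusted p = 0.271), quantile normalization (0.0575), DESeq2 (0.0562), without the 2 meristem ammonium libraries of experiments 3 and 4 (0.0572), and without each root cap control (0.227, 0.189 and 0.0521) or ammonium 1 (0.105), within a range of 0.00249 to 1 over its alternatives. The third, pp_58602, has the identifier next to pp_58601 and was named after its values were seen; it averaged 2.39 ± 1.15 and 0.0325 ± 0.0287. The 3 calls lie below the 16 false calls made with no simulated effect and, like 15 of those, had their highest mean in the root cap. Both edgeR's quasi-likelihood test on recovered reads (2024 at an unadjusted p under 0.05) and the limma fit of 6 libraries called 0. DESeq2 called 200, of which 52 were higher and 148 lower, a balance opposite to that of limma. Without 1 library the count was 0 (control 1, control 3 or ammonium 1 left out), 4 (control 4; 1 higher and 3 lower), 7 (ammonium 3) or 8 (ammonium 4), and pp_58601 had adjusted p = 0.105, 0.0605 and 0.0653 without control 1, control 3 and ammonium 1, within a range of 3.826e-12 to 0.755 over its alternatives.

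**Figure D2:**
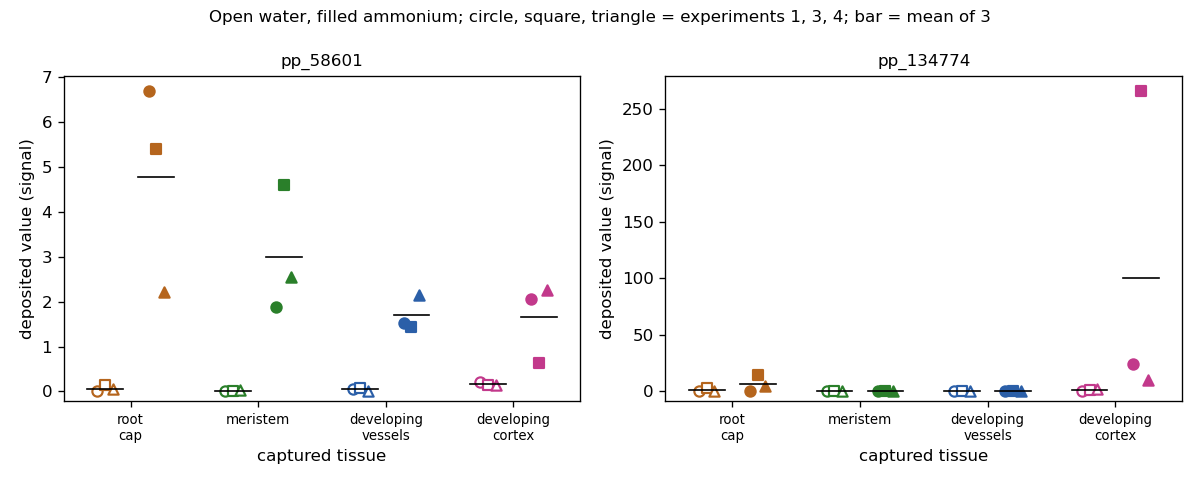
Deposited values (y axes, scaled signal, linear) of pp_58601 and pp_134774 in the 4 captured tissues (x axes); each point is a library, open for water and filled for ammonium, and bars are means of 3. The 12 ammonium libraries lie above the 12 control libraries for pp_58601, while the cortex mean of pp_134774 (100.05) is set by a single library at 266.

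In the developing cortex, 126 transcripts passed the threshold, 90 higher and 36 lower after ammonium. The greatest rises were in pp_134774 and pp_134778, with log2 differences of 4.26 (SE 0.82) and 4.15 (SE 0.85) and limma adjusted p = 0.0348 and 0.0436. Their ammonium means, 100.05 ± 144 and 95.0 ± 140 (SD, n = 3), had SDs above the means, against 1.28 ± 0.716 and 1.03 ± 0.347 with water. For pp_134774 the ammonium libraries of experiments 1, 3 and 4 held 24.3, 266 and 10.2, and without that of experiment 3 the log2 difference was 2.93 and the adjusted p 0.0691, within a range of 1.9483e-05 to 0.362 over its alternatives. The greatest falls were in pp_234650, from 8.18 ± 6.21 to 0.475 ± 0.312 (log2 difference -2.39, SE 0.50, adjusted p = 0.0473), and pp_143745, from 6.03 ± 0.688 to 0.419 ± 0.417 (-2.35, SE 0.44, adjusted p = 0.0295). The call of pp_234650 ended with pseudocounts 0.1 and 4 (adjusted p = 0.0759 and 0.0511), without controls 1 and 4 (0.197 and 0.205) and without ammonium 1 and 3 (0.187 and 0.0993), within a range of 0.00058161 to 0.320 over its alternatives. That of pp_143745 ended with pseudocount 0.1 (0.183), in DESeq2 (0.303) and in 5 of 6 fits without a library (0.0845 to 0.128), within a range of 0.00508 to 0.462. The calls of pp_134774 and pp_134778 likewise ended in 5 of 6 fits without a library (0.0691 to 0.127 and 0.0812 to 0.151) and with pseudocount 0.1 (0.0843 and 0.0863). That of pp_134778 also ended with pseudocount 4 (0.0709), within a range of 2.0123e-06 to 0.411, and its log2 difference was 2.72 without ammonium 3.

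Of the 90 transcripts called higher in the cortex, 80 (88.9%) had a higher mean in root cap controls than in cortex controls, and 22 were in the root cap-enriched set. Calls were made against the same cortex controls, which favours low cortex control values among rises, so the share among all tested transcripts (51.9%) is not the value without a change. Against the same cortex controls, 7 of the 90 (7.78%) were higher in meristem controls and 4 (4.44%) in vessel controls, against 48.5% and 55.2% of all tested transcripts, which is opposite to the direction that selection favours. Of the 36 called lower, 30 (83.3%) had a lower mean in root cap controls, 26 (72.2%) in meristem controls and 12 (33.3%) in vessel controls, against 48.1%, 51.5% and 44.8% of all tested. The 126 calls formed 101 runs of consecutive identifiers. Their number stands beside 16 false calls of the same fit with no simulated effect and 72 with simulated changes in the cortex. The simulation gave all groups the same dispersion, whereas the cortex ammonium libraries spread more than most other groups, so these false-call counts may be too low. Of those 16, 11 had their highest mean in the cortex, as did 32 of the 126 calls (28 higher and 4 lower), among them pp_134774, pp_134778, pp_234650 and pp_143745. In turn, edgeR's quasi-likelihood test on recovered reads called 0 (5331 at an unadjusted p under 0.05, lowest adjusted p 0.0601) and the limma fit of 6 libraries called 0, while DESeq2 called 1035 (470 higher and 565 lower), of which 93 were among the 126. Leaving out 1 library gave 1, 32 or 19 calls (controls 1, 3 and 4) and 28, 78 or 457 (ammonium 1, 3 and 4). Library weights gave 4754 (1963 higher and 2791 lower). Falls thus outnumbered rises with DESeq2 and with library weights, while rises outnumbered falls in each of these 6 fits without a library.

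In the meristem, 0 transcripts passed the threshold in limma, with 5626 at an unadjusted p under 0.05 and a lowest adjusted p of 0.113. edgeR's quasi-likelihood test on recovered reads also called 0 (6868 at an unadjusted p under 0.05), the limma fit of 6 libraries called 0 and DESeq2 called 784. The 95% interval of a log2 difference had a median half-width of 0.65 in this fit. It is the same in each tissue by construction, because the groups share an estimate of the spread. The meristem ammonium group had the widest spread (root mean square SD 0.77 on the log2 scale), so this half-width understates the uncertainty in the meristem. Without the meristem ammonium library of experiment 1 the count was 3171, without the control of experiment 4 it was 34, and without the control of experiment 3 it was 2. The 2 ammonium libraries then left, of experiments 3 and 4, correlated best with controls of other tissues: that of experiment 3 with cortex (r = 0.947 across transcripts, against 0.854 with meristem) and that of experiment 4 with root cap (0.898 against 0.882).

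In the developing vessels, pp_147764 alone passed the threshold. It averaged 4.29 ± 2.62 (SD, n = 3) with ammonium and 0.255 ± 0.171 with water, a log2 difference of 1.97 (SE 0.28, limma adjusted p = 0.0459). In the other 3 tissues its means lay between 0.114 and 0.512 under both treatments. A single call is below the 93 false calls made with no simulated effect and, like 91 of those, had its highest mean in the vessels; edgeR's quasi-likelihood test called 0 (1652 at an unadjusted p under 0.05), the limma fit of 6 libraries 0 and DESeq2 132. The call of pp_147764 ended without each control (adjusted p = 0.0643, 0.0742 and 0.119 for experiments 1, 3 and 4), without ammonium 3 (0.0616), without the 2 meristem ammonium libraries of experiments 3 and 4 (0.106), and with pseudocount 0.1 (0.334), median-of-ratios scaling (0.0563) or quantile normalization (0.142), within a range of 0.00045346 to 1 over its alternatives. The count was 136 (17 higher and 119 lower) without the ammonium library of experiment 1, 2 and 11 without those of experiments 3 and 4, and 4, 1 and 3 without the controls of experiments 1, 3 and 4. The single call without control 3 was lower after ammonium.

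Averaged over the 4 tissues, ammonium changed 0 transcripts by limma on 6 set means (3974 at an unadjusted p under 0.05, lowest adjusted p 0.208). The ammonium effect differed between tissues for 0 transcripts by the limma F test (1862 at an unadjusted p under 0.05, lowest adjusted p 0.959), and each of the 6 pairwise interactions gave 0 at the threshold. Library weights gave 5601 transcripts in the F test. The effects called in root cap, vessels and cortex are thus not shown to differ between tissues. Count tests were not run for these 2 results.

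Transcripts of the root cap list stood higher in the cortex after ammonium. The cortex ammonium library of experiment 1 correlated better with root cap controls (r = 0.942 across transcripts) than with cortex controls (0.928), and without it the mean difference of the list was 1.12 and not 1.68. Over all 916 enriched transcripts the mean was 1.02. Of 200 members, 197 had a higher mean with ammonium, with a median log2 difference of 1.57. By single transcripts, 7 were called over all tested transcripts and 48 when adjusted over the list alone, which is not independent evidence because the lists came from these libraries. The camera test with the preset correlation gave adjusted p = 3.2177e-39, but adjusted p = 0.634 with an estimated correlation, and fry gave adjusted p = 0.283. The list scored -1.59 ± 0.81 (SD, n = 3) in cortex ammonium libraries and -3.30 ± 0.98 in cortex controls, relative to root cap controls (exact permutation p = 0.2, 2-sided). The cortex list itself had a median difference of 0.00 in the cortex, with 101 members higher and 99 lower (1 and 3 past the threshold when adjusted over the list alone).

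Vessel list transcripts stood lower in the cortex after ammonium, with 188 of 200 lower and a median log2 difference of -0.87 (adjusted p = 5.3004e-17 by camera, adjusted p = 0.749 with an estimated correlation). Its mean was -1.01, and -0.38 over all 3090 enriched transcripts. In the cortex controls of experiments 1, 3 and 4 the vessel list scored -5.39, -4.17 and -3.87. With ammonium it scored -5.48, -5.33 and -5.48 (exact permutation p = 0.2, 2-sided). Control 1 lay within the ammonium range, so the lower mean score rests on higher scores in controls 3 and 4. The meristem list stood lower in the root cap, with 122 of 125 members lower and a median of -0.64 (adjusted p = 5.6017e-18 by camera, adjusted p = 0.711 with an estimated correlation). Its mean there was -0.63, and -0.34 without the root cap control of experiment 1. It also stood lower in the meristem itself, with 124 of 125 lower and a median of -0.79 (adjusted p = 9.4011e-18 by camera, adjusted p = 0.711 with an estimated correlation). Its mean difference in the meristem was -0.86, but -0.31 without the ammonium library of experiment 3 and -1.34 without that of experiment 1. Without both ammonium libraries of experiments 3 and 4, a meristem list made anew from the remaining libraries had a mean difference of 0.20. List and libraries changed together here, so this value does not show a turn of the same list. It also rests on 1 ammonium library, so the sign is that of a single library against 3 controls. The root cap and cortex lists had medians of 0.43 and 0.54 in the meristem, and the vessel list -0.46. Without those 2 libraries these lists were also made anew. Their mean differences, again of 1 ammonium library, were then -0.80, -0.02 and 0.21.

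Of the 16 list tests, 10 passed camera with the preset correlation, 0 with an estimated correlation and 0 by fry. The 6 of these 10 given without a p had adjusted p = 0.914 with an estimated correlation. The remaining medians, all between -0.37 and 0.18, were -0.05 for the root cap list, -0.22 for the vessel list and 0.16 for the cortex list in the root cap. In the vessels they were 0.04 for the root cap list, 0.18 for the meristem list, -0.37 for the vessel list and 0.06 for the cortex list, and the meristem list in the cortex had -0.08.

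**Figure D3:**
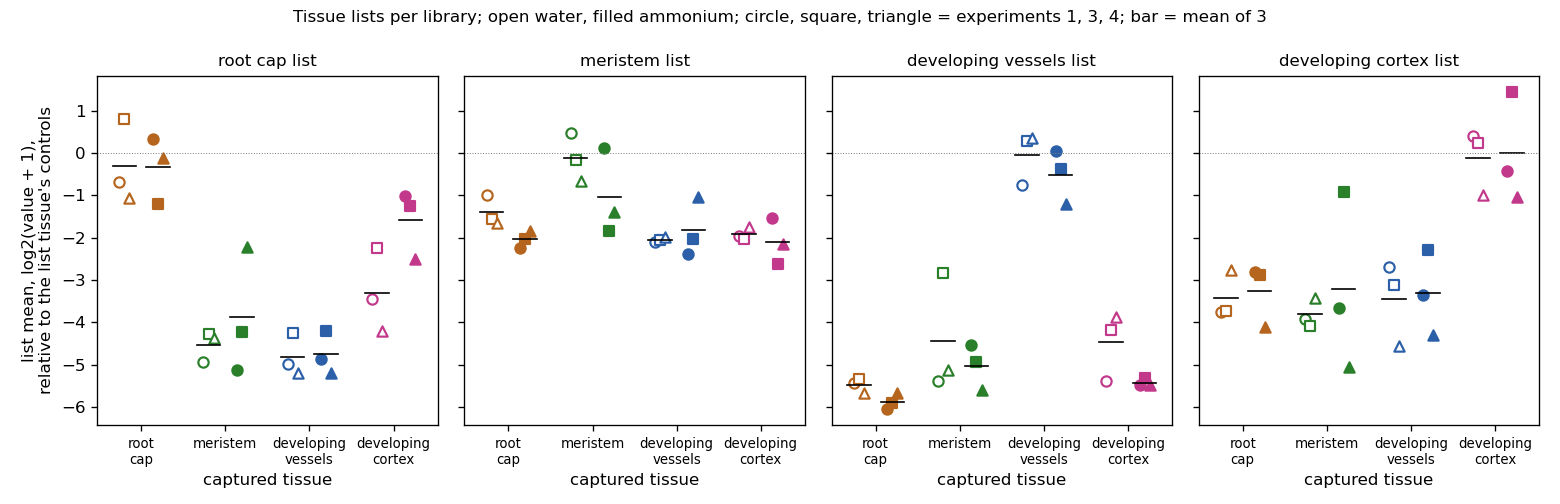
List scores (y axis, mean of log2(value + 1) relative to controls of the list's tissue) of the 4 tissue lists in each captured tissue (x axes); each point is a library, open for water and filled for ammonium, and bars are means of 3. In the root cap panel the cortex libraries average -1.59 with ammonium and -3.30 with water, and in the meristem panel the meristem libraries average -1.04 and -0.12. The meristem list held 23, 111 and 194 transcripts for experiments 1, 3 and 4.

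No transcript was called in more than 1 tissue in the same direction (0 in each of the 6 pairs). At an unadjusted p under 0.01, root cap and cortex shared 97 transcripts in the same direction (5.21 expected for independent lists), meristem and cortex 94 (23.3 expected), meristem and vessels 57 (4.53), root cap and meristem 49 (3.58), vessels and cortex 27 (6.37), and root cap and vessels 14 (1.04). Across transcripts, which are not independent, fold changes correlated with r from 0.235 (vessels and cortex) to 0.618 (root cap and meristem). Libraries of different tissues in a set deviated together from their group means (median r 0.278, with 31 of 36 pairs above 0.1), and other splits of the 6 sets into 3 and 3, chosen as a test after the counts were seen, also gave shared transcripts. At least 2 tissues shared 270 transcripts in the real split, and 82 to 287 in the 9 others. For 5 of the 6 pairs another split reached the real count: the highest others were 184 for root cap and meristem, 133 for meristem and cortex, 112 for meristem and vessels, 61 for vessels and cortex, and 21 for root cap and vessels. For root cap and cortex the others gave 19 to 55, against 97.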

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

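Leaving out the 2 meristem ammonium libraries together, and leaving out each library in turn for the tissue counts, were chosen after seeing the data. The cause was not tested for any change given here, except where fewer libraries or transcripts entered by construction. Among counts and list totals, 81 values moved by over 1.5 times and 183 did not. The averaged ammonium effect stayed at 0 in all of its alternatives; it was not run without the 2 meristem ammonium libraries. Single low transcripts rested on few reads: pp_58601 had 0 to 15 in each control library and at least 39 in each ammonium library.

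Calls in root cap, meristem, vessels and cortex (3, 0, 1 and 126) became 200, 784, 132 and 1035 with DESeq2, while edgeR gave 0 in root cap, vessels and cortex, as did the 6 libraries of the tissue. Pseudocount 0.1 gave 2 in meristem and 49 in cortex; pseudocount 4 gave 6 in root cap, 2 in meristem and 3 in vessels. A filter of 5 in 3 libraries gave 0 in root cap, 0 in vessels and 79 in cortex. Median-of-ratios scaling gave 0 in vessels, and quantile normalization 0 in vessels and 1 in meristem. Library weights gave 9 in root cap, 5 in vessels, 4754 in cortex and 5601 for the difference between tissues; the estimate of weights stopped before convergence, and weights ran from 0.176 (cortex ammonium 3) to 3.16 (cortex control 3). Leaving out the 2 meristem ammonium libraries gave 0 in vessels and 366 in cortex. Leaving out single libraries gave 0 to 8 in root cap, 0 to 3171 in meristem, 1 to 136 in vessels and 1 to 457 in cortex, and leaving out a set gave 0 to 11 for the difference between tissues (11 without ammonium 4, 4 without control 4 and 1 without ammonium 3). At an unadjusted p under 0.01 the shared transcripts rose from 0 to 270 by the looser threshold.

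A shared deviation of control and ammonium libraries by experiment number was not seen across the tissues. Control and ammonium libraries of a tissue with the same number had a median r of -0.092 between deviations, with 4 of 12 pairs above 0.1. In the cortex r was -0.219, 0.312 and 0.354 for experiments 1, 3 and 4. These pairs do not show that the numbers are unpaired. With the number as a replicate block, calls were 1 in root cap, 2 in vessels and 192 in cortex, and that of pp_119401 ended (adjusted p = 0.089).

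Counts of enriched transcripts in root cap, meristem, vessels and cortex (916, 125, 3090 and 862) became 237, 7, 1158 and 267 at a log2 difference of 2, and 519, 26, 1531 and 486 with pseudocount 4. The meristem count was 230 with pseudocount 0.1, 221 with quantile normalization, 545 with library weights, 473 in controls only and 895 without the 2 meristem ammonium libraries. A filter of 5 in 3 libraries gave 2014 in vessels. Leaving out a library or an experiment gave 456 to 1081 in root cap, 23 to 337 in meristem and 361 to 1008 in cortex; the vessel count stayed within 1.5 times.

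The list tests past the threshold went from 10 to 0 with an estimated correlation. Without the 2 meristem ammonium libraries the lists were made anew, and 1 ammonium library was left, assumed to vary like the other groups. The mean log2 differences of these new lists in the meristem were -0.80 (root cap list), 0.20 (meristem list), 0.21 (vessel list) and -0.022 (cortex list). Leaving out single libraries, with the lists kept, turned list means as well. In these fits camera with the preset correlation was adjusted over the 4 lists of the tissue concerned. Their threshold is therefore not that of the 16 tests adjusted together. In the root cap, the root cap list ran from -0.49 to 0.49 (past the threshold in each of these 6 fits) and the cortex list from -0.090 to 0.78 (0.21 with all libraries; past the threshold at 0.78 without control 4 and at 0.50 without ammonium 4). In the meristem, the root cap list ran from -0.58 to 0.86, the vessel list from -0.96 to 0.23 and the cortex list from -0.54 to 1.38. In the vessels, the meristem list ran from -0.18 to 0.39, the vessel list from -0.80 to 0.029 and the cortex list from -0.30 to 0.42. That cortex list (0.093 with all libraries) passed the threshold in both directions: at 0.42 without control 1, at 0.25 without ammonium 1 and at -0.30 without control 4. In the cortex, the cortex list ran from -0.59 to 0.47 and the meristem list from -0.43 to 0.19. The cortex list (0.087 with all libraries) passed the threshold at 0.47, 0.38 and 0.25 without ammonium 4, ammonium 1 and control 1. Without ammonium 3 it passed at -0.59. The meristem list (-0.12 with all libraries) passed at -0.43 without ammonium 1 and at -0.23 without control 1. Other called lists kept their sign in these fits: the root cap list in the cortex ran from 1.12 to 2.07, the vessel list in the cortex from -1.34 to -0.77, the meristem list in the root cap from -0.84 to -0.34 and in the meristem from -1.34 to -0.31, and the vessel list in the root cap from -0.55 to -0.24 (-0.38 with all libraries; lowest in size without control 1). With 50 transcripts per list, the root cap and vessel lists in the meristem lost the threshold (adjusted p = 0.142 and 0.0525). Of single transcripts and lists, 13 values reversed, 79 lost and 16 gained the threshold, and 501 did neither. For lists in fits without a single library, this tally uses the adjustment over 4 lists.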

Other observations

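Both label-swap tests, the 3 tests of tissue replacement and the splits for transcripts shared by tissues were chosen only after the results had been seen. The replacement test also changed the reading of root cap carry-over in the cortex, which had passed its earlier test and is treated here as undecided.

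Only 3 transcripts separated all 12 ammonium from all 12 control libraries, a set picked from the data. Transcripts pp_58601 and pp_58602, adjacent in number, were higher with ammonium: every ammonium library held at least 39 reads of each, and no control held more than 15 or 10. Transcript pp_212199 was lower, at 0.616 ± 0.467 against 1.64 ± 0.498 in root cap (SD, n = 3). Averaged over tissues, pp_58601 differed by 1.69 on the log2 scale (limma adjusted p = 0.208). Of the 10 splits of the 6 sets, 6 gave at least 3 such transcripts and the highest other gave 22, and the splits are too few for a share under 0.05. Library depth is argued against as the source, since pp_58601 had a Spearman correlation of 0 with reads per library.

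The meristem ammonium libraries of experiments 3 and 4 lay near cortex and root cap. A swapped label is argued against in both: the cortex library of the same set was closer to cortex than to meristem controls (difference of r -0.300), as was the root cap library to root cap (-0.158). Carried-over tissue stays open and may account for both, since 1 of the 20 most abundant cortex transcripts and 4 of 20 root cap transcripts lay below 0.25 of the median share (9.56% and 25.3%), and 5 was the bound set beforehand. That test separates weakly, as control libraries gave 0 to 5. The meristem control of experiment 4 had a median cortex share of 17.8%, above the 9.56%, with 0 of 20 transcripts below 0.25 of it. Those of experiments 1 and 3 had 1.34% and 0.606%, and median root cap shares of meristem controls were at most 0.725%. The list scores gave another share for the ammonium library of experiment 3, 52.4%, against 21.3% for that of experiment 4. The meristem list was lower than replacement by those shares needs, by -0.66 and -0.93 on the log2 scale. These values mix lists, as the list held 23, 111 and 194 transcripts for experiments 1, 3 and 4 while controls were averaged over all of them. On the same list, the ammonium and control libraries scored -1.85 and -0.16 in experiment 3, and -1.39 and -0.66 in experiment 4. A response to ammonium in these libraries stays open, untested.

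The root cap list was higher in the cortex after ammonium, where the library of experiment 1 correlated best with root cap controls. The authors' scaling is argued against, as the median log2 difference was at least 1.58 under 2 other scalings. Root cap tissue in the capture could bring the list up: at most 2 of 20 abundant transcripts lay below 0.25 of the median share in each library, whose median shares were 34.8%, 87.4% and 16.6%, against 2.15%, 18.1% and 2.08% for the mean of the cortex controls over the same transcripts and source libraries. Replacement by root cap would also lower the cortex list. The needed fall was taken from list scores relative to root cap controls, shares of 49.7%, 41.9% and 17.5% for experiments 1, 3 and 4. These are not the median shares above. The mean needed change was -0.68 on the log2 scale, while the mean change of the cortex list was 0.12. The difference was 0.81 (SD 1.49, n = 3). For experiments 1, 3 and 4 the list changed by -0.29, 1.57 and -0.91, where replacement needs -0.99, -0.78 and -0.28. These changes and their SD mix lists, as controls were averaged over the lists of all experiments. On the same list, the ammonium and control libraries scored -0.416 and 0.402 in experiment 1, and 1.442 and 0.230 in experiment 3. In experiment 4 they scored -1.0325 and -1.0047, nearly the same, so the larger fall given above is not shown there. The library of experiment 3 rose both ways, where a fall is needed, and that of experiment 1 fell both ways. With this spread between libraries, carry-over stays undecided. Carry-over and a cortex response to ammonium cannot be told apart with these 3 libraries.

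The 10 splits of 3 against 3 libraries or sets are too few for a share under 0.05. In the root cap 6 splits gave at least the real 3 calls (highest other 40), in the vessels 9 gave at least 1 (highest other 318), and in the cortex 1, the real split, gave 126 (highest other 47). In the meristem, the averaged effect and the difference between tissues the real count was 0, which all 10 splits reach by construction, so these splits decide nothing; the highest others were 1807, 5 and 20. At least 2 tissues shared 270 transcripts at an unadjusted p under 0.01, and 2 splits, the real one included, gave as many (highest other 287). The 1807 calls came with meristem controls 1 and 3 and ammonium 1 on a side, and the 318 with vessel control 1 and ammonium 3 and 4 on a side, which points to structure between libraries that the treatment does not describe. All 10 splits of the sets gave at least the real 10 list tests with the preset correlation (highest other 14), so that count does not set the treatment apart from other groupings.

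For the tissue counts, 100 draws of tissue labels within sets, the real one included, argued against an absence of any tissue difference. Mixed labels put the differences between tissues into the spread, so the draws do not test the size of each count. The real counts were reached by 1 draw in root cap (916, highest other 0), 1 in meristem (125, highest other 0), 1 in vessels (3090, highest other 0) and 2 in cortex (862, highest other 2037). The draw with 2037 had given the cortex label to 5 vessel libraries and 1 meristem library, and so recovered the vessel difference.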
